A study of Rattus norvegicus with 132 samples.

How the data were processed

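RNA was sequenced from colon and jejunum epithelium of Sprague Dawley rats. Per the labels, irradiated rats received abdominal radiation in 5 fractions of 4 Gy, and tissue was taken at day 4 or day 7. Compound Kushen powder, an oral herbal preparation that some sample descriptions call a pill, was compared with its oral vehicle. Compound Kushen injection, an injected preparation of the same name, was compared with its own injected vehicle (0.25% Tween-80 in 25 mM HEPES). The design holds 22 groups of 6 libraries, 132 libraries in all: non-irradiated, irradiated untreated, oral vehicle, powder, injected vehicle and injection, each per tissue and, except for the non-irradiated rats, per day.

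The deposited tables hold raw read counts per gene symbol, with no normalization, for 21837 genes in each of 2 tables. The authors' notes name the aligner STAR 2.7.10a and the rat genome build mRatBN7.2. The read counter, the annotation release and the strand setting are not given in the sources used here. The 2 tables hold 168 library columns, all matched to a label, and the 36 libraries that stand in both tables were used once. Gene positions are not in the tables, so genes are given by symbol alone. Total counts ran from 17.2 to 19.8 M per library, with a median of 19.14 M, so that precision is limited by the spread between rats and, for genes with a few counts, by counting error.

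The first digit of a library's name gave 3 library series. Every non-irradiated, untreated, oral vehicle and powder group holds 3 libraries of series 1 and 3 of series 2. All injected groups are of series 3, so injected groups were compared only with each other. Comparisons of 2 groups used the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM factors and the filterByExpr filter by group. Colon and jejunum were fitted apart: 42 libraries per tissue for irradiation, time, powder and oral vehicle with library series as a term, and 24 libraries per tissue for injection. Differences between tissues, days and preparations were tested as interaction contrasts with 84, 48, 42, 24 or 66 libraries in the fit. Genes are called where the Benjamini-Hochberg adjusted p over all genes tested is under 0.05, and every adjusted p of a gene comes from edgeR with this adjustment. Fold changes are those of the fit, with their standard error (SE), and levels are group means of CPM, the library-scaled counts of edgeR with TMM factors, with the standard deviation (SD) over n = 6 libraries. Where a group holds 0 counts of a gene, the fold is given as a lower bound against 3 counts over the group. Where it holds 1 to 3 counts, the ratio is given with its exact 95% counting interval. Such bounds and intervals cover counting error only. The p-values of genes measure the spread between libraries. The labels name no rats, and colon and jejunum libraries in the tissue interaction tests are not known to come from separate rats.

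Before the data were examined, 32 gene lists with 603 members were fixed: stem cell, mitosis, DNA replication, p53 targets, enterocyte absorption, colonocyte, goblet cell, Paneth cell and antimicrobial, enteroendocrine cell, tuft cell, regenerative epithelium, tight junction and adhesion, inflammatory cytokines and enzymes, interferon response, MHC class II, T cell, B and plasma cell, macrophage, neutrophil, mast cell, fibroblast and matrix, smooth muscle, endothelium, enteric nervous system, exocrine pancreas, NRF2 targets, xenobiotic metabolism, cholesterol synthesis, fatty acid oxidation, glucocorticoid response, circadian clock and immediate early genes. Of these members, 24 have no entry under their symbol in the deposited counts and are not analysed here, and 5 were found under an alias, among them Muc2, whose counts stand under AABR07006030.1. A list was tested where at least 3 members passed the filter. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 against all other genes, with camera at a correlation estimated for each list, and with fry, which asks whether the members move on balance in a single direction. List p-values are Benjamini-Hochberg adjusted over the lists of a comparison, and members are counted as called over all genes and adjusted over the list alone. Since camera sets the members against other genes, its p does not measure the spread between libraries alone. In arbitrary splits of the same samples camera at the preset correlation called a median of 9 to 13 lists per comparison, so its calls are given beside the member counts and the p with an estimated correlation.

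Also before the data were examined, a rule fixed the genes to be named. These are the 6 highest and 6 lowest fold changes among called genes with a symbol and a mean of at least 5 CPM (3 and 3 for the time and oral vehicle comparisons), up to 4 members with the smallest p of each list called by camera, and a panel in the irradiation comparisons (Cdkn1a, Mdm2, Lgr5, Olfm4, Mki67, Muc2, Reg3g, Il1b, with Slc26a3 in colon and Lct in jejunum). Where a comparison called 5 genes or fewer, all are named. Some genes that the rule names are not reported here.

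A radiation score was computed for each library: the mean log2 CPM (prior count 2) of genes higher in irradiated untreated than in non-irradiated libraries of that tissue and day, minus that of genes lower, for called genes with an absolute log2 fold change of at least 1. It was scaled so that the non-irradiated mean is 0 and the irradiated untreated mean is 1. Drug and vehicle scores were compared by a two-sided exact permutation test over the 924 arrangements of 6 against 6, adjusted by Benjamini-Hochberg over 8 comparisons. The genes of the score were chosen by a contrast of libraries that no drug comparison uses. The fit behind that contrast also held the oral vehicle and powder libraries, which shared in the filter, the scaling, the spread estimate and the series term.

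The alternatives were DESeq2 1.42.0 in place of edgeR, RLE factors in place of TMM, no low-count filter, a fit of only the 2 groups compared, the replicate number as a block, no library series term, each library series alone, leaving out each replicate number, other settings of the score, and list tests with RLE factors, the block or an estimated correlation. Chosen after seeing the data were the mitochondrial share of the counts as a covariate, leaving out the libraries with over 20% mitochondrial counts, and leaving out single libraries of the powder comparison in colon at day 4. Replicate numbers were checked for pairing over 2000 genes and did not pair the samples. In each of 330 pairs of libraries within a group the counts differed, and no 2 libraries were identical. The test was tried on simulated data of the powder comparison in colon at day 4, with 13208 genes. Known changes were set into 67 genes for 1.5-fold, 67 for 2-fold and 66 for 4-fold. Of these edgeR recovered 44.8%, 77.6% and 95.5%, with 3 false calls among 148. For the tissue difference of that comparison it recovered 47.8% of 2-fold changes, with 5 false calls among 114. Each simulated gene was drawn independently, so these false calls do not cover genes that move together between libraries, as in the real data. Injected groups were not compared with non-irradiated or untreated groups, since library series and group cannot be told apart there.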

Results

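Counts from 132 libraries of rat colon and jejunum epithelium were compared, 6 libraries in each of 22 groups. The groups were non-irradiated rats, rats given fractionated abdominal irradiation and nothing else, irradiated rats given oral vehicle or compound Kushen powder, and irradiated rats given injected vehicle or compound Kushen injection, at day 4 and day 7. The totals of the libraries lay between 17.2 and 19.8 M counts. The share of mitochondrial counts differed between groups: in colon it was 12.3% ± 1.25 (SD, n = 6) in non-irradiated, 9.16% ± 1.03 in irradiated untreated rats at day 4 and 3.95% ± 0.607 at day 7. In jejunum it was 12.3% ± 6.95, 12.7% ± 5.86 and 5.39% ± 1.83 in the same order. The non-irradiated jejunum libraries parted by library series, with 5.82% to 7.251% in series 1 and 12.46% to 20.91% in series 2. The comparison of irradiated with non-irradiated rats asks what irradiation changed, and the comparisons with vehicle ask what each preparation changed in irradiated rats.

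**Figure D1:**
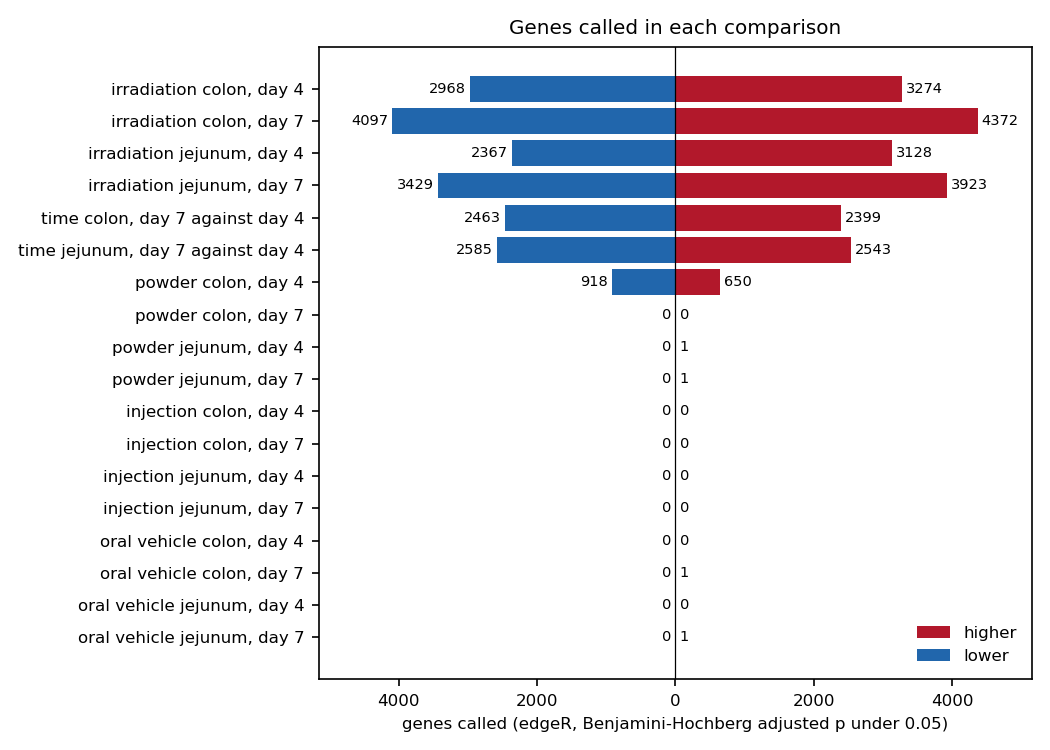
Number of genes called higher (red, right) and lower (blue, left) in each comparison, by the edgeR test with a Benjamini-Hochberg adjusted p under 0.05 (n = 6 libraries per group). The irradiation and time comparisons called between 4862 and 8469 genes, the powder comparison in colon at day 4 called 1568, and every other comparison called 1 or 0.

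In colon at day 4 after irradiation p53 targets rose and mast cell genes fell, the list calls of camera that held with an estimated correlation. Of the inflammatory genes 20 of 21 rose and of the neutrophil genes 7 of 7, and these list calls did not hold (camera adjusted p = 0.253 and 0.323). Ccng1, a p53 target of the cell cycle, rose 6.64-fold, from 65.3 ± 4.86 to 433 ± 44.4 CPM (SD, n = 6; log2 2.73 ± 0.20 SE, adjusted p = 4.38e-12). Phlda3, a p53-induced repressor of Akt, rose 92.6-fold, and Eda2r, a death receptor of the same pathway, 232-fold. Cdkn1a, the cell cycle inhibitor p21, rose 2.55-fold (log2 1.35 ± 0.18), and Mdm2, the ligase that degrades p53, 2.98-fold. The neutrophil-attracting chemokine Cxcl3 had 0 counts in the non-irradiated group and was at least 917-fold higher after irradiation, and the ratio for its relative Cxcl6 was 3650 (counting interval 654 to 144000).

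Of the 28 measured p53 targets 20 rose and 3 fell, with the same counts adjusted over the list alone (median log2 1.02, adjusted p = 0.0119 with an estimated correlation). All 6 measured mast cell genes fell, also adjusted over the list alone (adjusted p = 0.000174 with an estimated correlation). Their median log2 change was -5.75, or -4.90 with the gene at 0 counts set to its bound. Hdc, which makes histamine, fell 19.1-fold and Gata2, a mast cell transcription factor, 16.8-fold. The ratio of non-irradiated to irradiated counts was 350 (counting interval 62.4 to 13900) for the protease gene Cpa3 and 204 (56.1 to 1690) for Ms4a2, a chain of the IgE receptor. These are the calls of camera that held with an estimated correlation, 2 of the 14 called among 32 lists, while fry called 17.

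Among inflammatory cytokines and enzymes 20 of 21 rose and 0 fell (20 adjusted over the list alone, median log2 3.53), among them Il1a (177-fold), Lcn2, an iron-binding antimicrobial protein (14.5-fold), and Tnf (13.4-fold). All 7 measured neutrophil genes rose (7 adjusted over the list alone), among them S100a9, a subunit of calprotectin, 83.6-fold, and the granulocyte receptor Csf3r 12.3-fold. Interferon response genes rose in 13 of 28 cases and fell in 2 (13 and 3 adjusted over the list alone; adjusted p = 0.253 with an estimated correlation), with the interferon-induced GTPases Gbp5 and Gbp2 at 25.9-fold and 92.9-fold and the chemokine Cxcl10 at 19.6-fold. Macrophage genes rose in 11 of 16 cases (11 adjusted over the list alone; adjusted p = 0.556 with an estimated correlation), for example the Fc receptor Fcgr1a 9.27-fold.

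Of the genes of regenerative epithelium 19 of 22 rose (21 and 1 lower adjusted over the list alone, median log2 2.86; adjusted p = 0.323 with an estimated correlation). Anxa1, an anti-inflammatory annexin, rose 103-fold, and the epidermal growth factor receptor ligands Areg and Ereg 4.77-fold and 5.62-fold. Of the fibroblast and matrix genes 15 of 16 rose (15 adjusted over the list alone; adjusted p = 0.555 with an estimated correlation), for example Timp1, a metalloproteinase inhibitor, 8.90-fold and the collagen gene Col5a1 7.78-fold. DNA replication genes rose in 20 of 23 cases and mitosis genes in 15 of 22, with 20 and 15 adjusted over the list alone (1 replication gene fell over the list alone). Adjusted p with an estimated correlation was 0.554 and 0.588 for these lists. Rrm2, a subunit of ribonucleotide reductase, rose 5.46-fold and the mitotic cyclin Ccnb1 2.29-fold, while Mki67 was at 55.9 ± 11.0 CPM against 46.2 ± 17.3 (adjusted p = 0.373). Of 13 stem cell genes 6 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.586 with an estimated correlation). The Wnt targets Axin2 and Ascl2 rose 3.78-fold and 6.19-fold and Olfm4, which marks crypt base cells, 6.89-fold. For Lgr5, the intestinal stem cell receptor, the log2 difference was 1.24 ± 0.53 (adjusted p = 0.0521), and Rgmb, a bone morphogenetic protein co-receptor, fell 1.58-fold.

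Fatty acid oxidation genes fell in 12 of 18 cases (13 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation), among them Ehhadh, a peroxisomal enzyme, 4.10-fold. Circadian clock genes fell in 6 of 16 cases and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.323 with an estimated correlation), for example the repressor Cry2, 3.04-fold. Immediate early genes rose in 8 of 12 cases (8 adjusted over the list alone; adjusted p = 0.273 with an estimated correlation), for example the transcription factors Egr2 16.1-fold and Fos 2.74-fold. The genes with the lowest fold changes were Gkn3 (fell by 4.52 on the log2 scale), Azgp1, Itln1, a lectin of goblet cells, Zp2, Aldh1a7 and the calcium channel Cacna1h (fell by 3.53). Among the highest were also Pinlyp (ratio 1150, counting interval 318 to 9490), Atg9b (907, 251 to 7490) and Tnip3, an inhibitor of NF-kappa-B signalling (535, 183 to 2600).

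Lists without a camera call in colon at day 4 were as follows, with members risen and fallen: enterocyte absorption 6 and 4 of 20, colonocyte 2 and 6 of 19, goblet cell 1 and 2 of 15, Paneth cell and antimicrobial 4 and 1 of 8, enteroendocrine cell 5 and 1 of 16, tuft cell 1 and 0 of 10, tight junction and adhesion 5 and 0 of 18, MHC class II 0 and 0 of 8, T cell 2 and 1 of 14, B and plasma cell 2 and 7 of 13, smooth muscle 2 and 1 of 13, endothelium 5 and 0 of 11, enteric nervous system 1 and 1 of 9, exocrine pancreas 0 and 1 of 3, NRF2 targets 7 and 3 of 17, xenobiotic metabolism 6 and 7 of 21, cholesterol synthesis 1 and 2 of 22 and glucocorticoid response 2 and 2 of 10. Reg3g, an antimicrobial lectin, rose 83.7-fold, Muc2 was at 6544 ± 4740 against 4956 ± 1690 CPM (adjusted p = 0.412), Il1b rose 4.68-fold, and the chloride exchanger Slc26a3 was at 1543 ± 938 against 2070 ± 282 CPM (adjusted p = 0.628).

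In this comparison 6242 of 13306 genes were called, 3274 higher and 2968 lower, 46.9% of those tested. The high means of some genes came from single libraries of the irradiated group: Atp12a, a proton pump (3130-fold), reached 3910 CPM in replicate 4 and averaged 46.9 CPM in the others, and in replicate 6 Cxcl6 reached 134 and Anxa1 794 CPM, against means of 15.3 and 92.1 CPM in the others. The count was 2115 in library series 1 alone and 5289 in series 2 alone. It was 2847 with the mitochondrial share, which differs between these groups, as a covariate.

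In colon at day 7 after irradiation many proliferation and cholesterol genes rose, and many mast cell, T cell and fatty acid oxidation genes fell. Of the 9 camera calls only that of the mast cell genes held with an estimated correlation, and with the mitochondrial share as a covariate the count was 272 in place of 8469. All 22 mitosis genes rose (22 adjusted over the list alone, median log2 2.02; adjusted p = 0.544 with an estimated correlation), with Mki67 up 4.16-fold, from 46.2 ± 17.3 to 195 ± 32.7 CPM (SD, n = 6; log2 2.06 ± 0.24 SE, adjusted p = 7.79e-09). Of the DNA replication genes 21 of 23 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.584 with an estimated correlation), for example Rrm2 12.1-fold. Cholesterol synthesis genes rose in 17 of 22 cases (17 adjusted over the list alone; adjusted p = 0.769 with an estimated correlation), among them Idi1, an isomerase of the pathway, 3.65-fold. Fatty acid oxidation genes fell in 12 of 18 cases (12 adjusted over the list alone with 1 higher; adjusted p = 0.666 with an estimated correlation).

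All 6 mast cell genes fell again (6 adjusted over the list alone; adjusted p = 0.000808 with an estimated correlation), the list call at this day that held. Their median log2 change was -6.76, or -5.80 with the genes at 0 counts set to their bounds. Cpa3 and Ms4a2 had 0 counts at day 7 and were at least 130-fold and 152-fold lower. T cell genes fell in 10 of 14 cases and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.769 with an estimated correlation). Ccl5, a chemokine of cytotoxic T cells, fell 29.4-fold and Nkg7, of their granules, 16.9-fold, while Cd3g, a chain of the T cell receptor complex, rose 5.93-fold. All 16 fibroblast and matrix genes rose (16 adjusted over the list alone; adjusted p = 0.769 with an estimated correlation), for example Fn1, fibronectin, 34.0-fold. Inflammatory genes rose in 14 of 21 cases (15 adjusted over the list alone; adjusted p = 0.769 with an estimated correlation), with Il1a at 225-fold and a ratio of 3190 (counting interval 573 to 126000) for Nos2, the inducible nitric oxide synthase. Genes of regenerative epithelium rose in 18 of 22 cases and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 0.769 with an estimated correlation): Anxa1 rose 169-fold and Emp1, an epithelial membrane protein, fell 2.54-fold.

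The highest fold changes at day 7 in colon were those of Atp12a (745 ± 727 CPM against 0.117 ± 0.066), Fxyd4, a regulator of the sodium pump (3370-fold), Cxcl3 (at least 503-fold), Cxcl6 (ratio 2470, 443 to 97700) and Pinlyp (950, 263 to 7850). The lowest were Colec10, a collectin (846-fold), Edar, the ectodysplasin receptor (366-fold), Arhgap20 (232-fold), Bmper, a regulator of bone morphogenetic protein signalling (209-fold), Napsa, an aspartic protease (165-fold), and Tenm1 (152-fold). Olfm4 rose 20.5-fold, Lgr5 4.00-fold and Reg3g 21.4-fold, Muc2 fell 3.17-fold, Cdkn1a rose 1.44-fold and Mdm2 1.68-fold. Il1b (2.34-fold, adjusted p = 0.051) and Slc26a3 (adjusted p = 0.277) were not called. In all 8469 genes were called, 4372 higher and 4097 lower. Camera called 9 lists and fry 23. The group difference in mitochondrial share stands beside all of these changes.

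In jejunum at day 4 after irradiation 17 of 28 p53 targets, 17 of 28 interferon genes and 8 of 13 stem cell genes rose, and 11 of 14 goblet cell genes and 11 of 14 T cell genes fell. In these lists 2 p53 targets, 2 interferon genes and 1 stem cell gene fell, and 1 goblet cell and 1 T cell gene rose. Camera called 12 lists here, of which 0 held with an estimated correlation (fry called 16). Muc2, the main mucin of the gut, fell 10.8-fold, from 1974 ± 1610 to 172 ± 69.0 CPM (SD, n = 6; log2 -3.44 ± 0.47 SE, adjusted p = 8.69e-07), and Spdef, a transcription factor of goblet cells, 3.89-fold. Ccng1 rose 6.33-fold and Phlda3 73.3-fold, and Eda2r, with 0 counts in non-irradiated jejunum, was at least 132-fold higher. Axin2 rose 4.28-fold and Sox9, a crypt transcription factor, 9.41-fold. Of the 13 Paneth cell and antimicrobial genes 2 rose and 1 fell, Reg3g among the risen (5.54-fold).

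Goblet cell genes fell in 11 of 14 cases and 1 rose (12 and 2 adjusted over the list alone, median log2 -2.72; adjusted p = 0.63 with an estimated correlation), Capn9 12.9-fold and Bcas1 12.2-fold among them. Of 28 p53 targets 17 rose and 2 fell (17 and 3 adjusted over the list alone, median log2 0.71 with or without Eda2r at its bound; adjusted p = 0.102 with an estimated correlation), and Cdkn1a and Mdm2 rose 1.62-fold and 1.85-fold. Interferon response genes rose in 17 of 28 cases and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.63 with an estimated correlation). Cxcl10 rose 23.3-fold and Mx2, an antiviral GTPase, 12.1-fold. T cell genes fell in 11 of 14 cases and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.63 with an estimated correlation): Cd8a, the co-receptor of cytotoxic T cells, fell 8.88-fold and Cd3e, of the receptor complex, 8.71-fold, while Cd3g rose 7.31-fold.

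Stem cell genes rose in 8 of 13 cases and 1 fell (11 and 2 adjusted over the list alone), mitosis genes in 19 of 22 (20 adjusted over the list alone), DNA replication genes in 15 of 23 (18), genes of regenerative epithelium in 10 of 18 (10), inflammatory genes in 10 of 14 with 1 lower (10 and 1) and smooth muscle genes in 5 of 12 (6). Cholesterol synthesis genes fell in 8 of 22 cases (8 adjusted over the list alone) and enterocyte absorption genes in 4 of 25 (2). For each of these 8 lists, adjusted p with an estimated correlation was 0.63, except 0.932 for enterocyte absorption. Clu, a marker of regenerating crypts, rose 38.8-fold, Il33 5.68-fold, Lcn2 40.1-fold, Nos2 253-fold and the muscle myosin gene Myh11 4.28-fold, while the fructose transporter Slc2a5 fell 5.30-fold and Fdft1, squalene synthase, 2.98-fold. Olfm4 fell 5.68-fold. Lgr5 (adjusted p = 0.0861), Mki67 (0.148), Il1b (0.556) and Lct, lactase (1098 ± 1180 against 4094 ± 451 CPM, 0.095), were not called.

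The highest fold changes in jejunum at day 4 were those of Pinlyp (0 counts in the non-irradiated group, at least 529-fold), Fgf19, an intestinal hormone of bile acid control (ratio 3530, counting interval 634 to 140000), Ly6al (1230-fold), Ly6i (250-fold) and Plat, tissue plasminogen activator (141-fold). The lowest were Slc22a7, an organic anion transporter (30.7-fold), Cabp2 (20.5-fold), Slc37a2 (13.7-fold) and Fam111a (12.2-fold). Fam111a ran from 0.159 to 318 CPM between the irradiated libraries and from 285 to 1410 CPM between the non-irradiated ones. Its deviations from the group means also correlated at 0.907 between colon and jejunum libraries of the same number, so its fold depends on which libraries the group holds. In all 5495 of 12501 genes were called, 3128 higher and 2367 lower, and 31 lists were tested. The count was 3496 with only the 2 groups in the fit, 1880 in library series 1 alone and 5495 in series 2 alone.

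In jejunum at day 7 tuft cell genes fell, the only list call of camera here that held with an estimated correlation. Most T cell and MHC class II genes fell and all mitosis and DNA replication genes measured rose, and these list calls did not hold. Tuft cells are chemosensory cells: Trpm5, their taste channel, fell 30.2-fold, from 17.3 ± 8.51 to 0.569 ± 0.597 CPM (SD, n = 6; log2 -4.92 ± 0.53 SE, adjusted p = 5.3e-09), Dclk1 fell 20.2-fold, Gnat3, gustducin, 117-fold, and Sucnr1, the succinate receptor, had 0 counts and was at least 75.7-fold lower. Tuft cell genes fell in 10 of 11 cases (10 adjusted over the list alone, median log2 -3.37 with or without Sucnr1 at its bound) with adjusted p = 0.0342 with an estimated correlation.

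T cell genes fell in 13 of 14 cases and 1 rose, with the same counts adjusted over the list alone (median log2 -4.33; adjusted p = 0.35 with an estimated correlation). Cd8a fell 110-fold, Ccl5 48.8-fold and Tbx21, a transcription factor of type 1 responses, 24.5-fold. The granzymes Gzmf and Gzma, with Cd7 and Plek, were also among the lowest, at 47.8-fold, 38.1-fold, 38.4-fold and 46.9-fold. MHC class II genes fell in 7 of 8 cases (7 adjusted over the list alone; adjusted p = 0.663 with an estimated correlation), for example the invariant chain Cd74, 8.11-fold. Enterocyte absorption genes fell in 13 of 25 cases (11 adjusted over the list alone) and enteroendocrine genes in 11 of 17 with 1 higher (11 and 1), each with adjusted p = 0.854 with an estimated correlation. Apoa4, a lipoprotein component, fell 4.32-fold, Alpi, intestinal alkaline phosphatase, 3.79-fold, Lct 7.51-fold and the incretin gene Gip 5.03-fold, while Neurog3, which specifies enteroendocrine precursors, rose 8.53-fold.

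Mitosis genes rose in 22 of 22 cases, DNA replication genes in 23 of 23 and stem cell genes in 11 of 13, with the same counts adjusted over the list alone (adjusted p = 0.663 with an estimated correlation for each). Mki67 rose 5.12-fold, Rrm2 25.8-fold, Olfm4 8.11-fold and Prom1, a marker of crypt progenitors, 6.38-fold. Lgr5 was at 0.946 ± 0.829 against 0.453 ± 0.182 CPM (adjusted p = 0.0795). Cholesterol synthesis genes rose in 15 of 22 cases and 1 fell (16 and 1 adjusted over the list alone), Idi1 5.30-fold among them, and smooth muscle genes in 7 of 12 (9), Smtn, smoothelin, 4.51-fold among them, each with adjusted p = 0.785 with an estimated correlation. Cdkn1a and Mdm2 fell 1.52-fold and 1.29-fold, Muc2 6.84-fold and Il1b 4.58-fold, and Reg3g was not called (adjusted p = 0.0718). The highest fold changes were those of Fgf19 (ratio 1470, counting interval 264 to 58100), Ly6al (1020-fold), Anxa10 (609, 208 to 2950), Tff1, a stomach trefoil peptide (250-fold), Hspb1, a small heat shock protein (94.7-fold), and Etv4 (64.0-fold), and Slc22a7 fell 141-fold. In all 7352 genes were called, 3923 higher and 3429 lower. Camera called 10 of 31 lists and fry 14. The count was 3303 in library series 1 alone and 7443 in series 2 alone.

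**Figure D2:**
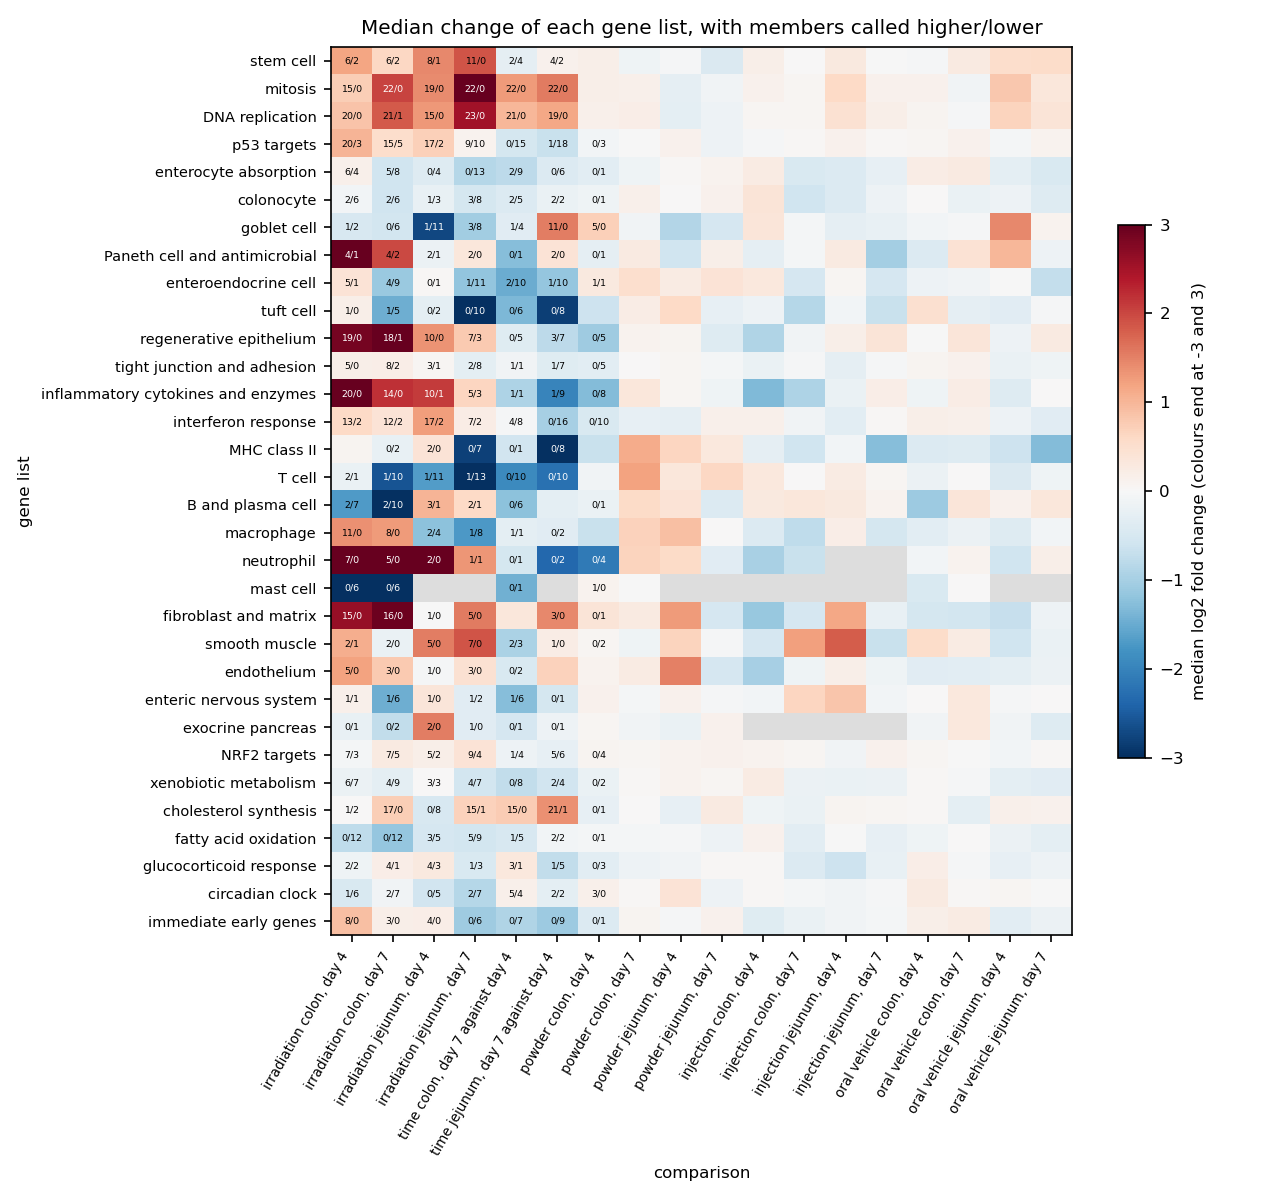
Median log2 fold change of the tested members of each gene list (vertical axis) in each comparison (horizontal axis, n = 6 libraries per group), with the members called higher/lower printed where any was called. Grey cells had fewer than 3 members tested. Mitosis genes were higher in all 22 tested members at day 7 in both tissues, and mast cell genes were lower in all 6 in colon at both days.

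The 2 tissues differed in their response to irradiation. At day 4 the interaction test called 2994 of 13741 genes, 1865 with a positive difference of the log2 changes (jejunum minus colon) and 1129 with a negative one, and at day 7 it called 5437, 3487 and 1950. The sign does not say in which tissue a gene changed. Goblet cell genes had negative differences in 11 of 15 cases at day 4 and 1 positive (median difference -2.27), and macrophage genes in 11 of 16 cases at day 4 and in 14 of 16 at day 7, with 1 positive each (median difference -2.39 and -2.50). At day 7 mitosis genes had positive differences in 13 of 22 cases and fatty acid oxidation genes in 11 of 19, while tuft cell genes had negative ones in 6 of 11 and MHC class II genes in 5 of 8. Among 28 p53 targets 11 had negative and 4 positive differences at day 7.

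Between day 4 and day 7 after irradiation many p53 targets fell and many cholesterol synthesis genes rose in both tissues. The list calls held with an estimated correlation in jejunum and not in colon (adjusted p = 0.284 for p53 targets and 0.467 for cholesterol synthesis in colon). In jejunum p53 targets fell in 18 of 28 cases and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.0371 with an estimated correlation), for example Mdm2, 2.39-fold, and Cdkn1a, from 388 ± 71.4 to 157 ± 35.5 CPM (SD, n = 6; log2 -1.30 ± 0.16 SE, adjusted p = 2.39e-07). Cholesterol synthesis genes rose in 21 of 22 cases and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0371 with an estimated correlation). Sqle, squalene epoxidase, rose 5.12-fold. Tuft cell genes fell in 8 of 11 cases (9 adjusted over the list alone, median log2 -2.82 with or without Sucnr1 at its bound; adjusted p = 0.0315 with an estimated correlation), Trpm5 30.3-fold and Sucnr1 at least 26.4-fold among them. These are the 3 of 14 camera calls in jejunum that held.

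Of the others in jejunum, MHC class II genes fell in 8 of 8 cases (8 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), Cd74 11.4-fold. T cell genes fell in 10 of 14 (11 adjusted over the list alone) and immediate early genes in 9 of 11 (9), both with adjusted p = 0.347 with an estimated correlation, for example Prf1, perforin, 10.0-fold and the stress factor Atf3 4.46-fold. Goblet cell genes rose in 11 of 14 (11), mitosis genes in 22 of 22 (22), and interferon response genes fell in 16 of 28 (17), inflammatory genes in 9 of 14 with 1 higher (9 and 1) and enteroendocrine genes in 10 of 17 with 1 higher (11 and 1), with adjusted p = 0.414 with an estimated correlation for each. Atoh1, the secretory lineage factor, rose 3.37-fold and Top2a, topoisomerase, 4.05-fold, while Ifit3 fell 5.13-fold, Ccl20 4.69-fold and Ghrl, ghrelin, 4.42-fold. DNA replication genes rose in 19 of 23 (20 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation), genes of regenerative epithelium fell in 7 of 18 with 3 higher (7 and 3; 0.748) and tight junction genes in 7 of 18 with 1 higher (7 and 1; 0.589), for example the claudin Cldn4, 4.40-fold. The extremes also held Olfm4 (46.1-fold higher), Anxa10 (34.8-fold higher), Plek (28.0-fold lower) and Akp3, an alkaline phosphatase (20.9-fold lower). In jejunum 5128 genes were called, 2543 higher and 2585 lower. The count was 2973 without replicate 2, 3341 without replicate 5 and 2918 without replicate 6. It was 2807 with only the 2 groups, 166 in library series 1 alone and 5617 in series 2 alone. The list tests were not repeated within a single series.

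In colon p53 targets fell in 15 of 28 cases (16 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation), for example Ccng1, 2.03-fold, and the proapoptotic Bbc3, 1.91-fold. Mitosis genes rose in 22 of 22 cases (22), Mki67 3.48-fold among them, and T cell genes fell in 10 of 14 (11), Ccl5 12.3-fold among them, both with adjusted p = 0.284 with an estimated correlation. DNA replication genes rose in 21 of 23 (21), cholesterol synthesis genes in 15 of 22 (16), and enteroendocrine genes fell in 10 of 16 with 2 higher (10 and 2), enteric nervous system genes in 6 of 9 with 1 higher (6 and 1), xenobiotic metabolism genes in 8 of 21 (8) and immediate early genes in 7 of 12 (7), each with adjusted p = 0.467 with an estimated correlation and the counts adjusted over the list alone in brackets. Acat2, an acetyl-CoA transferase, rose 2.50-fold, while the granin Chga fell 4.13-fold, the synaptic gene Snap25 3.71-fold, Aldh1a1, a retinal dehydrogenase, 19.6-fold and Btg2 1.95-fold. Fxyd4 rose 86.9-fold and Rnf152 13.0-fold, and S100g, a calcium-binding protein, fell 77.8-fold, Colec10 79.0-fold and Cxcl13, a B cell chemokine, 171-fold. In colon 4862 genes were called, 2399 higher and 2463 lower. Fry called 17 lists in colon and 16 in jejunum. With the mitochondrial share as a covariate the colon count was 575 and Rnf152 changed direction.

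In colon at day 4, 8 of 21 inflammatory genes, 10 of 28 interferon genes and 4 of 7 neutrophil genes were lower with compound Kushen powder than with oral vehicle. Of the 7 camera calls 0 held with an estimated correlation (adjusted p = 0.548, 0.226 and 0.846 for these lists). Nos2 fell 22.4-fold, from 4.51 ± 3.64 to 0.175 ± 0.214 CPM (SD, n = 6; log2 -4.49 ± 0.93 SE, adjusted p = 0.00293). Il1a fell 6.70-fold and the chemokines Cxcl6, Cxcl3 and Cxcl1 32.8-fold, 30.8-fold and 4.99-fold. Ifit3 and Ifit2, interferon-induced antiviral genes, fell 6.74-fold and 3.89-fold, and Gbp2 9.93-fold, each with 0 of 6 powder libraries above the vehicle median. S100a9 fell 5.74-fold and S100a8 5.19-fold.

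Inflammatory genes fell in 8 of 21 cases (13 adjusted over the list alone, median log2 -1.29, fry adjusted p = 0.00962; adjusted p = 0.548 with an estimated correlation), interferon response genes in 10 of 28 (10 adjusted over the list alone, median log2 -0.45, fry adjusted p = 0.000915; adjusted p = 0.226 with an estimated correlation) and neutrophil genes in 4 of 7 (4 adjusted over the list alone, median log2 -2.11, fry adjusted p = 0.0364; adjusted p = 0.846 with an estimated correlation). Genes of regenerative epithelium fell in 5 of 22 cases (6 adjusted over the list alone), among them Anxa1, 5.94-fold, Plaur, the urokinase receptor, 3.22-fold, and Cd55 2.16-fold. Tight junction and adhesion genes fell in 5 of 18 (10 lower and 1 higher adjusted over the list alone), among them Cldn4, 2.08-fold, Dsg2, 1.51-fold, and Cdh1, E-cadherin, 1.36-fold. Macrophage and tuft cell genes had 0 members called (0 adjusted over the list alone). For these 4 lists adjusted p was 0.846 with an estimated correlation. Camera called 7 lists, all lower, and goblet cell genes, not among them, rose in 5 of 15 cases (6 and 2 lower adjusted over the list alone).

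The highest fold changes with powder in colon at day 4 were those of Colec10 (log2 2.79 ± 0.91, higher in 5 of 6 libraries), Wfdc1 (2.25 ± 0.65), Ccn3, a matricellular protein (1.97 ± 0.54), A4gnt, which glycosylates gland mucins (1.92 ± 0.50), Ros1, a receptor kinase (1.80 ± 0.38), and Zcchc12 (1.78 ± 0.32). The lowest were those of Cyp24a1, which degrades vitamin D (93.7-fold), Fer1l4 (30.8-fold), Tgm1, transglutaminase (30.1-fold), and Slc15a1, the peptide transporter (19.5-fold), beside Cxcl6 and Cxcl3. The ratio for the neutrophil receptor Cxcr2 was 20.4 (counting interval 6.63 to 102). Single vehicle libraries carried the means of the lowest genes: replicate 5 held 201 CPM of Cxcl6, 118 of Cxcl3, 544 of Tgm1 and 91.1 of Fer1l4, against means of 7.25, 5.19, 7.72 and 3.66 CPM in the other vehicle libraries, and replicate 6 held 212 CPM of Cyp24a1 against 7.54.

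In this comparison 1568 genes were called, 650 higher and 918 lower. Of the 918 lower with powder 619 were higher after irradiation at day 4 in the untreated rats, where independent sets would share 225.9, and of the 650 higher 391 were lower after irradiation, where 145.0 would be shared. Genes move together between libraries, and with the libraries permuted the correlation of powder and irradiation effects across genes, -0.608, had exact permutation p = 0.117 (Benjamini-Hochberg adjusted p = 0.387). These permutations did not hold library series fixed. Without single vehicle libraries the count was 941 (replicate 1), 2474 (replicate 2), 520 (replicate 5) and 979 (replicate 6), and without single powder libraries 982 (replicate 2) and 633 (replicate 4). It was 958 with only the 2 groups compared, 3 in library series 1 alone, 25 in series 2 alone and 651 with the mitochondrial share as a covariate, which was 8.40% ± 1.88 with vehicle and 9.58% ± 1.99 with powder.

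In the other powder comparisons few genes were called. Kprp, a keratinocyte protein, rose in jejunum at day 4 from 0.0654 ± 0.0819 to 6.16 ± 7.76 CPM (log2 6.39 ± 1.01, adjusted p = 0.0026, higher in 6 of 6 libraries), as the only gene called. It was also the single gene called for the difference between powder and injection there. Its call ended with only the 2 groups, in library series 1 (0 genes each), in series 2 (17 other genes) and without replicate 3 (0). Without replicate 1 the count was 2, Kprp among them. Rusc1 in jejunum at day 7 rose 1.47-fold, from 264 ± 22.7 to 391 ± 50.6 CPM (log2 0.56 ± 0.10, adjusted p = 0.034, higher in 6 of 6 libraries), a call that ended (0 genes) with no low-count filter, no library series term, only the 2 groups, the replicate block or a single library series, and without replicate 1, 2, 5 or 6. Without replicate 4 it was lost too, with 2 other genes called. In colon at day 7 edgeR called 0 genes, 462 had an unadjusted p under 0.05, and DESeq2 called 2. The unadjusted numbers in jejunum were 521 at day 4 and 446 at day 7, and DESeq2 called 16 and 1.

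Camera called 12 lists for powder in colon at day 7, 18 in jejunum at day 4 and 15 in jejunum at day 7, fry called 0 in each, and 2 calls held with an estimated correlation. In colon at day 7 these were the T cell genes, with 0 of 14 members called and 2 higher adjusted over the list alone (median log2 1.20, adjusted p = 0.0484 with an estimated correlation). They were, for jejunum at day 4, the tuft cell genes, with 0 of 11 called and 0 adjusted over the list alone (median log2 0.61, adjusted p = 0.0296 with an estimated correlation). MHC class II genes in colon at day 7 had 0 of 8 members called and 7 higher adjusted over the list alone (median log2 1.11; adjusted p = 0.1 with an estimated correlation).

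The powder effect differed between the tissues at day 4 in 55 of 13741 genes by the interaction test, 39 with a positive difference (jejunum minus colon) and 16 with a negative one. Nos2 (log2 difference 5.33 ± 1.30, adjusted p = 0.0442) and Slc15a1 (4.04 ± 0.90, adjusted p = 0.0263) had positive differences, and the goblet cell genes Spdef (-1.88 ± 0.43) and Spink4 (-2.58 ± 0.60) negative ones, adjusted p = 0.0323 each. These 4 genes were chosen after their values were seen. The count was 17 with only the compared groups in the fit, where other splits of the samples called up to 1022, 192 with DESeq2, 36 without the low-count filter and 107 with colon and jejunum libraries of the same number as a block. For the tissue difference at day 7 edgeR called 0 genes (257 at an unadjusted p under 0.05, DESeq2 0). For the difference between the days it called 0 in colon (2099 unadjusted, DESeq2 183) and 0 in jejunum (406 unadjusted, DESeq2 1).

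For compound Kushen injection no gene was called in either tissue at either day. In colon edgeR called 0 genes at day 4 and at day 7, with 475 and 227 at an unadjusted p under 0.05, and DESeq2 called 0 and 0. In jejunum edgeR called 0 and 0, with 1012 and 342 unadjusted, and DESeq2 called 9 and 2. Inflammatory genes in colon at day 4 had 0 of 22 members called and 4 lower adjusted over the list alone (median log2 -1.32; adjusted p = 0.345 with an estimated correlation), and smooth muscle genes in jejunum at day 4 0 of 12 and 6 higher (median log2 1.82; adjusted p = 0.745 with an estimated correlation). In jejunum at day 7 MHC class II genes had 0 of 8 called and 5 lower adjusted over the list alone (median log2 -1.27; adjusted p = 0.454 with an estimated correlation), and Paneth cell and antimicrobial genes 0 of 13 and 5 lower (median log2 -1.02; adjusted p = 0.806 with an estimated correlation). Camera called 11, 16, 7 and 12 lists in colon at day 4 and 7 and in jejunum at day 4 and 7, of which 0 held with an estimated correlation, and fry called 0. The mitochondrial share in jejunum at day 4 was 18.5% ± 9.06 with vehicle and 21.8% ± 8.86 with injection, above 20% in 2 and 3 libraries.

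The difference between powder and injection, each against its own vehicle, was called for 0 genes in colon at day 4 (845 at an unadjusted p under 0.05, DESeq2 3), 0 in colon at day 7 (625, DESeq2 0), 1 in jejunum at day 4 (Kprp, 408, DESeq2 1) and 0 in jejunum at day 7 (650, DESeq2 0). Route, vehicle and library series differ between the preparations, and their doses are not in the labels used. For injection the tissue difference was called for 0 genes at day 4 and day 7 (1049 and 169 unadjusted, DESeq2 0) and the difference between days for 0 in colon and jejunum (418 and 512 unadjusted, DESeq2 0).

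Oral vehicle was compared with irradiation alone. In jejunum at day 4 goblet cell genes had 0 of 14 members called over all genes and 12 higher adjusted over the list alone (median log2 1.43, fry adjusted p = 0.0191; adjusted p = 0.116 with an estimated correlation), and Paneth cell and antimicrobial genes 0 of 13 and 6 higher (median log2 0.99; adjusted p = 0.658 with an estimated correlation). In jejunum at day 7 MHC class II genes had 0 of 8 called and 5 lower adjusted over the list alone (median log2 -1.29; adjusted p = 0.682 with an estimated correlation). At day 7 Nlrx1, a mitochondrial regulator of innate immune signalling, was the single gene called in each tissue. It rose from 10.5 ± 3.32 to 170 ± 176 CPM in colon (log2 4.09 ± 0.74, adjusted p = 0.0342) and from 5.13 ± 0.966 to 248 ± 211 CPM in jejunum (log2 5.61 ± 1.01, adjusted p = 0.0303), above the untreated median in 5 of 6 libraries each. Not all libraries shared the rise: replicates 3 and 4 of oral vehicle held 12.6 and 8.56 CPM in colon and 5.03 and 5.29 in jejunum. These values lie within the ranges of untreated irradiated libraries at day 7, 5.38 to 15.4 CPM in colon and 3.71 to 6.70 in jejunum. The Nlrx1 level also ran from 8.34 to 499 CPM in colon and from 5.07 to 302 CPM in jejunum with powder at day 7, and from 4.96 to 307 CPM and from 3.86 to 227 CPM with injected vehicle. With the replicate block the count was 0 in both tissues. The Nlrx1 call was also lost in both tissues with only the 2 groups and in each library series alone, and in colon without the library series term. In colon it was lost without replicate 1, 3, 5 or 6 (0 genes each) and without replicate 2 (1 other gene). In jejunum it was lost without replicate 1, 2, 5 or 6 (0 each), and without replicate 4 there were 2 genes, Nlrx1 among them. At day 4 edgeR called 0 genes in both tissues, with 374 and 1150 at an unadjusted p under 0.05, and DESeq2 called 0 and 0.

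**Figure D3:**
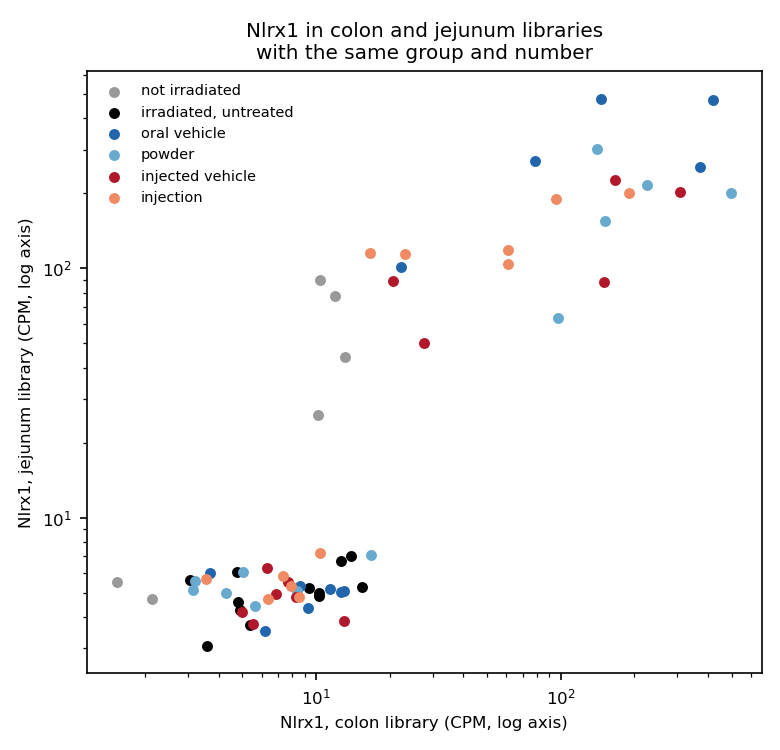
Nlrx1 level in CPM (both axes logarithmic) in the colon library (horizontal) and the jejunum library (vertical) that share a group and a number, 66 pairs, coloured by treatment with days pooled. The libraries of irradiated untreated rats lie at or under 15.4 CPM in colon, and the highest oral vehicle libraries reach 421 CPM in colon and 480 in jejunum.

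The radiation score, on which non-irradiated libraries average 0 and irradiated untreated libraries 1, was lower with powder than with oral vehicle in colon at day 4. It was 0.677 ± 0.175 with powder and 1.01 ± 0.268 with vehicle (SD, n = 6 each), a difference of -0.337 ± 0.131 (SE) with exact permutation p = 0.026, which did not pass the adjustment over 8 comparisons (Benjamini-Hochberg adjusted p = 0.208). All 6 powder libraries lay under the vehicle median, and the difference was -0.355 in library series 1 and -0.319 in series 2. The permutations did not hold library series fixed, although the score differed between series. It was 0.537 with powder and 0.892 with vehicle in series 1, and 0.817 and 1.14 in series 2. For injection in colon at day 4 the score was 0.896 ± 0.258 against 1.12 ± 0.342 (difference -0.224, exact permutation p = 0.234, adjusted 0.55). The remaining 6 comparisons had differences between -0.0648 and 0.132 and adjusted exact p-values between 0.476 and 0.781.

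**Figure D4:**
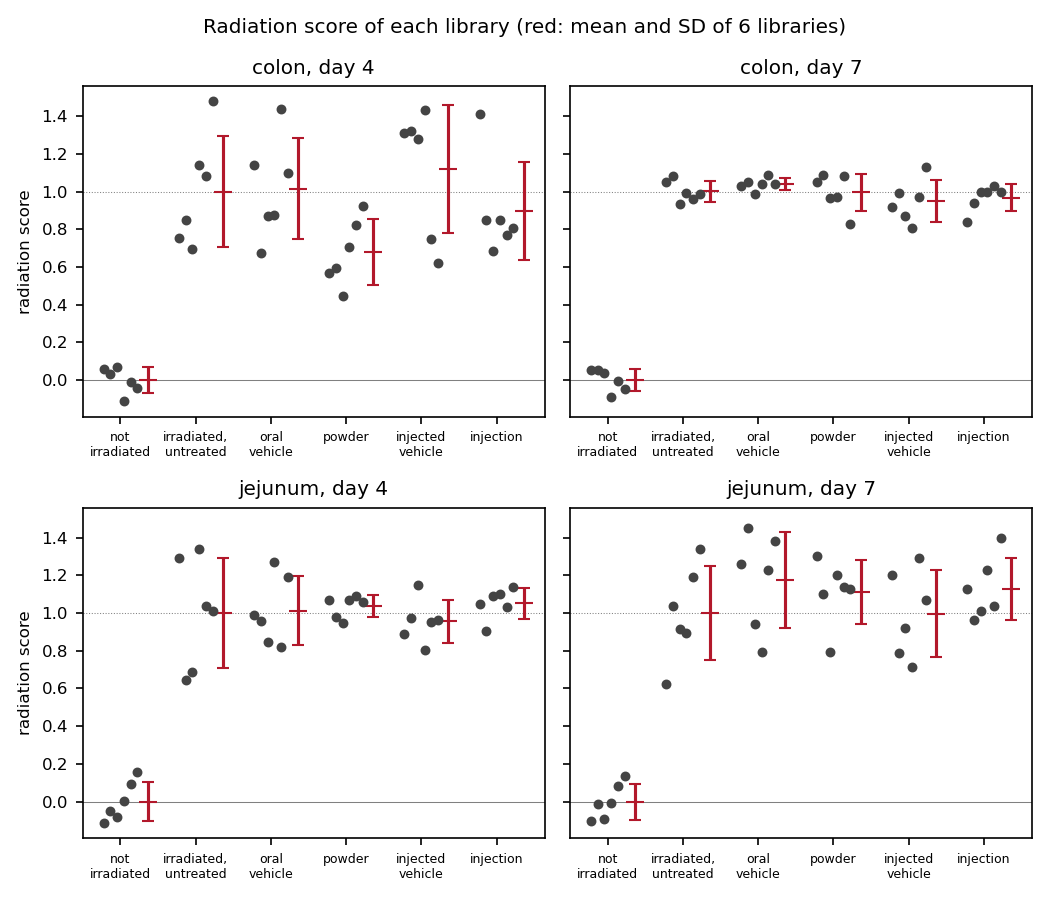
Radiation score of each library (vertical axis, no unit) by treatment (horizontal axis) in 4 panels for tissue and day, as grey points, with the mean and SD of 6 libraries in red. Non-irradiated libraries are scaled to 0 and irradiated untreated libraries to 1. In colon at day 4 powder libraries lie between 0.448 and 0.921 and oral vehicle libraries between 0.672 and 1.44.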

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

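The tests of the share of non-epithelial cells, of the share of epithelium and of Nlrx1, the mitochondrial covariate and the leaving out of single powder or vehicle libraries were chosen after the results were seen. The bounds for the mitochondrial share and for the library series were written before. The 2 bounds for the series overlap and the value met both, so that test is left undecided.

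Irradiation changed jejunum and colon differently by the interaction test, in 2994 genes at day 4 and 5437 at day 7. With only the compared groups in the fit it did so in 1978 and 5283 genes. Other splits of the samples called at most 1 and 23, and 1 of 24 splits, the real one, called as many at each day. These splits mix irradiated with non-irradiated libraries within each tissue, which also removes the response common to both tissues. They therefore cannot decide on the tissue difference by itself, which rests on the interaction test. The powder effect differed between the tissues at day 4 in 55 genes. With only the compared groups in the fit it did so in 17, and 2 of 24 splits called as many, the highest other 1022, so chance is not excluded there. These splits did not keep colon and jejunum libraries of the same number together, while the fit with that number as a block called more than the 55 genes. A split that calls 1022 genes points to a structure of the samples. The difference between powder and injection in jejunum at day 4 was called for 1 gene, Kprp, and with only the compared groups for 0, so that all 24 splits called as many. For powder minus injection in colon at day 7 the 2-group fits called 1 gene in the real split alone (highest other 0), and for the other interaction tests, with 0 genes, all 24 splits called as many.

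Single libraries lay far from the others of their group in 8 of 64 checks, where chance marks about 1 in 20 groups. Total counts were 18.3 M in replicate 4 of irradiated untreated jejunum at day 7 (median of the others 19.6), 18.5 in replicate 4 of oral vehicle jejunum at day 4 (19.1), 17.2 in replicate 4 of oral vehicle colon at day 7 (19.3), 18.2 in replicate 6 of injection colon at day 4 (19.1) and 19.4 in replicate 6 of injection jejunum at day 7 (19.7). Mitochondrial counts made up 19.6% in replicate 5 of injected vehicle colon at day 4 (9.87% in the others) and 9.15% in replicate 6 of injection jejunum at day 7 (6.31%). The radiation score of replicate 1 of injection colon at day 4 was 1.41 (0.807 in the others).

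In the split tests with 60 splits the real one alone called as many genes for irradiation in colon at day 4 (6030, highest other 0) and day 7 (8313, 3369), in jejunum at day 4 (3496, 1271) and day 7 (6541, 4719), for time in colon (3876, 1405) and for powder in colon at day 4 (958, 320), and 2 of 60 did for time in jejunum (2807, 4187). The share is under 0.05 in each of these, not adjusted over the 18 comparisons, which argues against chance without excluding it. For time in jejunum this is narrow, since another split called more genes than the real one. For oral vehicle at day 7 the fit of only the 2 groups called 1 gene in each tissue, which was not Nlrx1, and 3 of 60 splits in colon (highest other 2904) and 2 of 60 in jejunum (6424) called as many. These splits decide nothing about the Nlrx1 call. Splits with 2904, 6424, 2868 (injection jejunum, day 4), 4450 (injection jejunum, day 7) and 2529 (powder colon, day 7) genes point to a structure of the samples. For the comparisons with 0 genes all 60 splits called as many.

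With powder in colon at day 4, 8 of 21 inflammatory, 10 of 28 interferon and 4 of 7 neutrophil genes were lower, and 0 of 7 list calls held with an estimated correlation. Whether an effect of a single library series is the whole of it is not decided, since the value meets both bounds written for that test. Across genes the effects in series 1 and series 2 correlated at 0.584 (one-sided exact permutation p = 0.045, 18 of 400 arrangements), while other arrangements reached 0.672. The radiation score differed by -0.355 ± 0.142 in series 1 and -0.319 ± 0.175 in series 2 (SE; exact permutation p = 0.1 and 0.2, where 0.1 is the smallest possible). A difference in mitochondrial share cannot be told apart, since 41.1% of the called genes were still called with it as a covariate, between the bounds of 20% and 50%. With it Nos2 went from -4.49 ± 0.93 to -3.97 ± 0.99 and Ifit3 from -2.75 ± 0.50 to -2.29 ± 0.53 (log2, SE), both still called, while S100a9 went from -2.52 ± 0.57 to -1.73 ± 0.62 and Cxcl6 from -5.03 ± 1.11 to -3.20 ± 1.20, both with smaller folds and no longer called (adjusted p = 0.0878 and 0.102). A lower share of all non-epithelial cells may account for part of it, and would lower both neutrophil and fibroblast genes. The mean log2 level changed by -1.05 for neutrophil genes (exact p = 0.00649) and by 0.0187 for fibroblast and matrix genes (exact p = 0.959). The neutrophil change minus the fibroblast change was -1.07 ± 0.574 (exact p = 0.0909), too wide to decide. An effect of the preparation stays open beside these.

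Fibroblast and matrix genes rose in irradiated colon at day 4 while mast cell genes fell. A lower share of epithelium alone would raise both. The fibroblast change minus the mast cell change was 5.85 ± 0.355 (exact p = 0.00216, the smallest 6 against 6 can give), which argues against it as the only source of both changes. The mast cell genes may have fallen separately, so the test cannot decide whether a lower share raised the fibroblast genes. A lower share of epithelium and a change in the fibroblasts or in their number stay open, and no test here parts these.

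Nlrx1 differed between libraries of a group, from 8.56 to 421 CPM in oral vehicle colon and from 5.03 to 480 CPM in oral vehicle jejunum at day 7. An error of single libraries is argued against, since colon and jejunum libraries that share a number deviated together (permutation p = 1e-05, the smallest these permutations can give). A difference between rats shared by both tissues may be the source, as a hypothesis with the same test. Wide ranges were not limited to oral vehicle: at day 7 Nlrx1 ran from 8.34 to 499 CPM in colon and 5.07 to 302 in jejunum with powder, from 4.96 to 307 and 3.86 to 227 with injected vehicle and from 6.36 to 190 and 4.73 to 200 with injection, and from 4.72 to 90.0 in non-irradiated jejunum. In untreated irradiated rats at day 7 it ran from 5.38 to 15.4 and 3.71 to 6.70. A part of oral vehicle in it stays open.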

How the results depend on the processing

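The mitochondrial covariate, the exclusion of libraries over 20% mitochondrial counts and of single libraries of powder colon at day 4 were chosen after the data were seen. Of 382 named gene results 381 kept direction and call with DESeq2, 382 with RLE factors, 377 without the low-count filter, 374 with the replicate block, 377 without the library series term, 253 in series 1 alone, 325 in series 2 alone and 289 with the mitochondrial covariate, where 92 lost the call and 1 reversed: Rnf152 with time in colon (log2 -0.458). Of 32 counts of called genes 32 stayed within 1.5-fold with RLE factors, 22 with DESeq2 and 29 without the filter. Where a value below differs, the cause was not tested. A single series or a left-out replicate holds fewer samples, but series 1 and series 2 each hold 3 libraries per group. In jejunum series 2 alone called 5495 and 7443 genes for irradiation at day 4 and day 7 and 5617 for time. Fewer samples therefore do not account for the lower jejunum counts of series 1.

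With the mitochondrial covariate the counts were 2847 for irradiation colon day 4, 272 for day 7, 575 for time in colon, 651 for powder colon day 4 (645 shared with the 1568) and 3 for powder jejunum day 4. In colon the share follows the groups (12.3%, 9.16% and 3.95%), so the covariate takes up part of the comparison itself.

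With only the 2 groups the counts were 3496 for irradiation jejunum day 4, 2807 for time in jejunum, 958 for powder colon day 4 and 0 for powder jejunum day 4 and day 7. In series 1 alone they were 2115 for irradiation colon day 4, 1880 and 3303 for irradiation jejunum day 4 and day 7, 166 for time in jejunum, 3 for powder colon day 4, 0 for powder jejunum day 4 and day 7, 2 for oral vehicle colon day 4 and 1 for oral vehicle jejunum day 4. In series 2 alone they were 3022 for time in colon, 25 for powder colon day 4, 17 and 0 for powder jejunum day 4 and day 7, 2 for oral vehicle colon day 7, and 1 and 2 for oral vehicle jejunum day 4 and day 7.

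DESeq2 called 2 for powder colon day 7, 16 for powder jejunum day 4, 9 and 2 for injection jejunum day 4 and day 7, 2 for oral vehicle colon day 7 and 5 for oral vehicle jejunum day 7. It called 192 for the tissue difference of powder at day 4, 183 for the day difference of powder in colon, 3 for powder minus injection in colon at day 4 and 1 for the day difference of powder in jejunum. Without the low-count filter the counts were 0 for powder jejunum day 7, 36 for the tissue difference of powder at day 4 and 1 for powder minus injection in colon at day 4. With the block they were 0 for powder jejunum day 7 and oral vehicle colon and jejunum day 7, and 107 for the tissue difference of powder at day 4. Without the series term they were 0 for powder jejunum day 7 and oral vehicle colon day 7 and 2 for oral vehicle jejunum day 7.

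Leaving out 1 replicate number gave 4865 to 5861 for irradiation colon day 4, 7776 to 8241 for day 7, 4109 to 5681 and 5822 to 7495 for irradiation jejunum day 4 and day 7, and 3766 to 4905 for time in colon. For time in jejunum it gave 2918 to 6388 (2973 without replicate 2, 3341 without 5, 2918 without 6), and for powder colon day 4 548 to 1829 (622 without replicate 1, 548 without 3, 985 without 4, 633 without 5). It gave 0 to 2 for powder jejunum day 4 and day 7, 0 to 1 for oral vehicle colon day 7 and 0 to 2 for oral vehicle jejunum day 7. Leaving out 1 library of powder colon day 4 gave 941, 2474, 520 and 979 without vehicle replicates 1, 2, 5 and 6, and 982 and 633 without powder replicates 2 and 4. Without libraries of over 20% mitochondrial counts the counts were 3672 and 6887 for irradiation jejunum day 4 and day 7 and 6148 for time in jejunum.

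With an estimated correlation camera called 2 lists for irradiation colon day 4, 1 for day 7, 0 and 1 for irradiation jejunum day 4 and day 7, 0 and 3 for time in colon and jejunum, 0 and 1 for powder colon day 4 and day 7, 1 and 0 for powder jejunum day 4 and day 7, and 0 for each injection and oral vehicle comparison. Of 204 list results 201 were the same with RLE factors and 200 with the block.

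The radiation score difference changed sign for powder colon day 7 in series 1 (0.0149), for powder jejunum day 4 with the genes of the other day (-0.0533) and in series 2 (-0.0223), and for powder jejunum day 7 in series 2 (0.026), none of them past its test. Total counts ran from 17.2 to 19.8 M and mitochondrial shares from 2.97% to 38.0%, so the counts left for other genes differed between libraries. For genes with few counts, such as Cpa3 and Cxcl3, counting error limits the fold.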

Other observations

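The tests in this part were chosen after the values were seen.

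Ly6al, Aldh1a1 and Clca4 differed between the tissues in their change after irradiation. Ly6al differed by 9.56 ± 0.75 at day 4 and 9.53 at day 7 on the log2 scale: it rose in jejunum by 10.26 and 9.99. At day 7 Aldh1a1 differed by 8.59 ± 0.85 and Clca4, of the calcium-activated chloride channel family, by -7.62 ± 0.69.

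Colon and jejunum libraries with the same number may come from the same rat. Of 12407 genes 36 had deviations from their group means that correlated above 0.7 over 66 numbers, against at most 2 in 1000 shuffles. Among them were H3f3c (0.966), Irak4 (0.917), Lman1 (0.913), Fam111a (0.907), Nlrx1 (0.897) and RT1-N2 (0.855).

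The injection and powder effects in colon at day 4 correlated at 0.583 across genes (exact permutation p = 0.169, Benjamini-Hochberg adjusted p = 0.654). Whether both preparations shift the same genes cannot be told apart from chance by this test. Camera at the preset correlation called up to 21 lists in arbitrary splits, and in 0 comparisons did the real split call the most.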
